A study of Drosophila melanogaster with 6 samples.

How the data were processed

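Gene expression was measured in whole Drosophila melanogaster embryos at stage 16 on 1-colour Affymetrix arrays, with 2 arrays for each of 3 genotypes. The groups, taken from the sample labels, were wild type (strain w1118), grh mutant (allele grhB37) and grh overexpression driven by 69B, a GAL4 driver line. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase, reverse transcribed with random primers and labelled with biotin. The labels name 2 replicates per genotype but do not say whether they came from separate embryo collections, so the p-values measure only the spread between these samples, which may be technical.

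The deposited table holds 1 value per probe set and array, 18952 probe sets in all, on what the values show to be a log2 scale. GCRMA and MAS5 are named in the submitters' processing notes without role, order or version. The scale and the absence of centring per gene were read from the values, which ran from 2.27, a floor shared by all arrays, to 14.1. The array medians were 3.00 and 2.99 for wild type, 3.10 and 3.08 for grh mutant, and 3.16 and 3.15 for grh overexpression, and the share of probe sets at the floor lay between 33.01% and 33.35%. The deposited log2 values were used as they are, with no further normalization. Scanner files were not used here. No unit of depth applies to arrays, and the number of arrays limits the precision.

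Probe sets were named from the platform annotation, with symbols updated through gene identifiers to the reference gene table of assembly Release 6 plus ISO1 MT. Of the probe sets, 13647 had 1 gene symbol, 402 had several, 4720 had none in that annotation and 183 were array controls, which were left out of the tests. The update gave a current symbol for 13544 probe sets, and 103 kept the symbol of the annotation. No gene was named from a probe set with several symbols. The genome build behind the probe sets is not given in the sources used here, and genome positions were not used here.

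The probe set with the highest mean over the 6 arrays stood for a gene, and probe sets with no symbol or several stayed as unnamed rows. Of 17104 rows, those with a log2 value of at least 4 on at least 2 arrays were tested, which left 8632 rows, 7644 of them named genes. A 3-group means model was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). It left 3 residual degrees of freedom, and the prior added 7.93. The 3 contrasts were grh mutant minus wild type, grh overexpression minus wild type and grh overexpression minus grh mutant, each with Benjamini-Hochberg adjustment, and a row was called at an adjusted p under 0.05. All p-values are two-sided. An exact permutation of 2 arrays against 2 cannot give a p below 0.333, so no such test was run. Means are given with the SD over 2 arrays. A group with both arrays under 4 was treated as dim: the fold is then written "at least", from the mean of the bright group against the higher of 4 and the dim group's mean. Apart from the 3' and 5' control probe sets, no level of one probe set was set against that of another. Directions, calls and the order of the largest changes rest on fitted values, so a dim gene's place in that order is not settled. Counts of higher and lower genes include genes dim in both groups. A gene dim in 2 groups entered the tests only through the remaining group, so the direction of its change in that group was fixed by the filter.

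Before the data were examined, 23 gene lists were fixed from general knowledge of the fly: septate junction, apical polarity and adherens junction, chitin synthesis and cuticle assembly, cuticle protein families, catecholamine and pigmentation, epidermal wound response, earlier described Grh targets, denticle and zona pellucida domain, trachea, Osiris family, innate immunity, ecdysone pathway, cell cycle, heat shock and stress, ribosomal proteins, germline and maternal transcripts, and markers of neurons, glia, muscle, hemocytes, fat body, midgut and salivary gland. Some lists share genes and are not separate lines of evidence: kkv and Ddc, for example, are both wound response genes and earlier described Grh targets. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 23 lists of a contrast. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes.

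The genes named were set by a rule, also fixed before the data were examined. It takes grh in every sample, then the 10 named genes with the largest increase and the 10 with the largest decrease in each contrast against wild type among called genes whose groups do not overlap. It adds the 2 to 4 members of each described list with the largest absolute log2 fold change, the genes vvl, Ddc, ple, kkv, stit and w, and for genes called in both contrasts the 6 with the largest smaller change in opposite directions and the 6 in the same direction. The 5 largest increases and 5 largest decreases measured on both sides were added after the data were examined. So were genes named to show a limit of a result, and the genes of the observations on tyrosine degradation, alkaline phosphatases and maltases.

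The fit was tested on simulated data with the 8632 rows and the spread of these arrays. Of 100 genes changed by 1 log2 unit, 100% were called in each contrast. Of 100 changed by 0.3, 68% were called for grh mutant minus wild type, 74% for grh overexpression minus wild type and 69% for grh overexpression minus grh mutant. Among unchanged rows 0.107%, 0.142% and 0.119% were called. All other rows were left unchanged in the simulation, whereas in the data at least 80.11% of rows were called in each contrast. The adjusted p depends on that share, so the simulated rates do not give the error rate of the calls made here.

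The alternatives were no filter, a filter at 6, quantile normalization, median centring, no intensity trend, robust hyperparameters, a fit of only the 4 arrays compared, the mean of a gene's probe sets, every probe set as a row, a replicate block, each array left out in turn, an adjusted p under 0.1, and an added minimum of 1 log2 unit. Intervals of medians are 95% bootstrap intervals from 10000 resamples of genes. Medians and counts of 2-fold changes are also given with dim genes at their bound, a choice made after the data were examined, where a gene dim in both groups counts as 0. Differences between tissue markers were taken for the 6 pairs of muscle, neuron, glia and hemocyte markers, with intervals also widened by Bonferroni to hold over the 6 pairs together. Figures were drawn with Python 3.11.15.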

Results

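The series measured transcript levels in stage 16 Drosophila embryos of 3 genotypes, to find the effect of Grainy head (Grh), a transcription factor of epidermal differentiation, and compared a grh mutant and a grh overexpression strain with wild type. There were 2 arrays per genotype, 6 in all. No group carried the driver without grh overexpression, and the labels do not say whether the strains share a genetic background. Differences between the groups are therefore differences between strains. An effect of grh cannot be told apart from one of strain background, driver line or embryo collection. Replicate arrays correlated across probe sets at r = 0.99944 for wild type, 0.999453 for grh mutant and 0.999408 for grh overexpression, where probe sets are not independent replicates. The median absolute log2 difference between replicates was 0.0697, 0.059 and 0.0663, against 0.488 between grh mutant and wild type, 0.461 between grh overexpression and wild type and 0.692 between the 2 altered genotypes.

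The grh probe set used for testing read 7.41 ± 0.06 (SD, n = 2) in wild type, 9.03 ± 0.02 in the arrays labelled grh mutant and 12.33 ± 0.08 in grh overexpression, on the log2 scale. It was therefore 3.09-fold higher in the arrays labelled grh mutant (limma adjusted p = 1.59e-10) and 30.2-fold higher in grh overexpression (adjusted p = 1.21e-14). The other grh probe set was dim in every group, at 3.25 ± 0.05, 3.53 ± 0.02 and 2.46 ± 0.10. The labels do not say what the mutant allele does to the transcript or to the part the probes read, so the higher value does not check the mutant label, and directions drawn from these arrays rest on the label. The array holds no probe set with stit or w as its only symbol, so these were not analysed here. The probe set for ple, which encodes tyrosine hydroxylase, stayed at 2.38 in all 3 groups, under the minimum for testing.

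**Figure D1:**
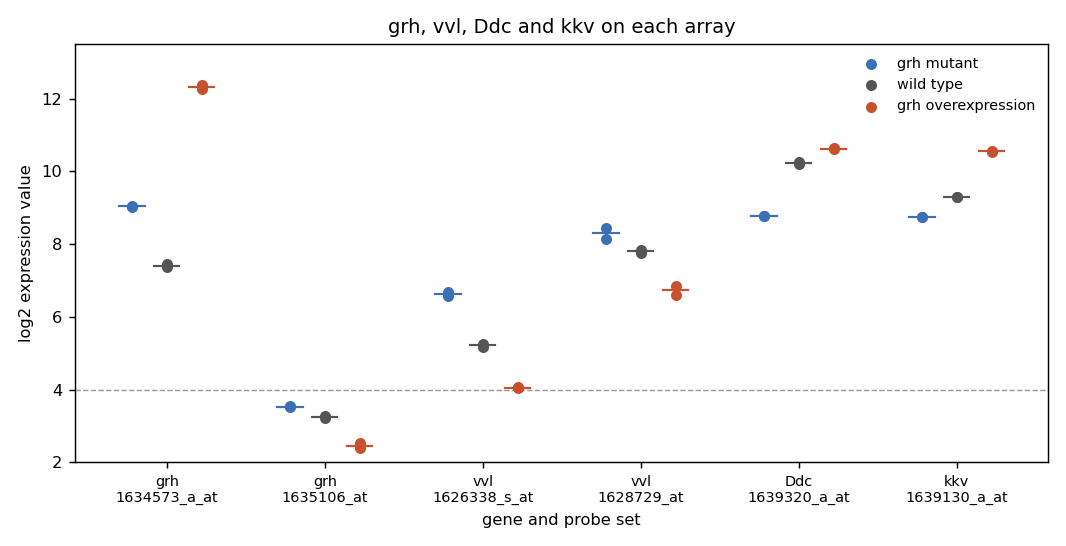
Log2 expression value (vertical axis) of each probe set for grh, vvl, Ddc and kkv (horizontal axis) on the 6 arrays; points are arrays, short lines are group means of 2 arrays, and the dashed line marks the filter at 4. Ddc averaged 8.77 in grh mutant, 10.23 in wild type and 10.62 in grh overexpression, while vvl on its brighter probe set averaged 8.30, 7.81 and 6.73.

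The first comparison asked which transcripts differ between the arrays labelled grh mutant and wild type. Gfat1, which starts the hexosamine route to chitin, was 7.80-fold lower (log2 fold change -2.96, adjusted p = 3.44e-13), and Gnpnat, a later enzyme of that route, was 6.12-fold lower. The dopa decarboxylase gene Ddc fell from 10.23 ± 0.03 to 8.77 ± 0.01 (2.74-fold, adjusted p = 7.29e-11), and the chitin synthase gene kkv fell from 9.30 ± 0.01 to 8.74 ± 0.00 (1.47-fold, adjusted p = 1.79e-07). The mitotic cyclin genes CycB and CycB3 fell by 3.59 and 3.20 log2 units, while all 12 tested muscle markers rose. The gene vvl, which encodes a POU factor needed in the trachea, rose by 0.49 log2 units on its brighter probe set (adjusted p = 0.000794), and its other probe set read 6.621 ± 0.074 in grh mutant, 5.215 ± 0.057 in wild type and 4.057 ± 0.012 in grh overexpression.

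Among the 10 largest fitted decreases, CG13946 was at least 15.8-fold, CG9877 at least 10.5-fold, yellow-d2 at least 9.46-fold, CG30148 at least 8.68-fold, Lcp65Ad at least 8.51-fold, Cyp4p2 at least 6.84-fold and CG7763 at least 6.79-fold lower, each being dim in grh mutant. CG15282 was 26.2-fold, CG9757 22.4-fold and the Tweedle cuticle protein gene TwdlQ 18.7-fold lower, with both groups measured. CG17919 and gfzf, named because both groups were measured, were 13.3-fold and 12.8-fold lower. Among the 10 largest fitted increases, the peroxiredoxin gene Prx6c rose from 8.37 ± 0.23 to 12.72 ± 0.05 (20.3-fold, adjusted p = 3.12e-12). CG32237 was 19.9-fold, CG7465 18.03-fold, the mucin gene Muc26B 16.1-fold, CG13227 14.4-fold and CG33521 12.4-fold higher. The genes CG4835 (at least 10.98-fold), alpha-Est2 (at least 9.67-fold), CG42329 (at least 4.97-fold) and CG32284 (at least 3.94-fold) were dim in wild type.

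Of 24 tested genes for chitin synthesis and cuticle assembly, 6 were higher and 14 lower in grh mutant (median log2 fold change -0.35, camera adjusted p = 0.117). The chitin-binding protein gene obst-B fell by 2.43 log2 units, and the chitinase gene Cht5 rose by 2.50. Of 15 catecholamine and pigmentation genes 4 were higher and 9 lower (median -0.69, or -0.44 with dim genes at their bound, adjusted p = 0.131), and yellow-d and amd fell by 1.69 and 1.53 log2 units, while yellow-e2 was at least 1.35-fold lower. Of 6 epidermal wound response genes 1 was higher and 4 lower, with Gadd45 at -1.498 and puc at 1.44. Among 10 earlier described Grh targets, 6 were higher and 3 lower. The chitin organizing gene knk was 2.83-fold lower, and dpp and cora rose by 1.10 and 0.72. The median of that list was 0.37, its mean -0.01, and fry gave it a downward direction. Of 83 cuticle protein genes, 35 were higher and 27 lower, and TwdlH and Cpr11A rose by 3.21 and 2.48.

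Among epithelial genes, 12 of 22 septate junction genes were higher and 8 lower, with bark at 1.77, hoka at 1.10, yrt at 0.99 and crok at -0.96. Of 12 apical polarity and adherens junction genes, 7 were higher and 4 lower, with crb at 1.02, alpha-Cat at 0.89 and p120ctn at -0.79. Of 14 denticle and zona pellucida domain genes 9 were higher and 2 lower, with zye at 1.79 and tyn, dim in wild type, at least 2.83-fold higher, and of 12 tracheal genes 7 were higher and 2 lower, with esg at 1.498 and knrl at 1.45. The Osiris family had 8 higher and 3 lower of 15, with Osi7 at 1.36 and Osi12, dim in grh mutant, at least 1.25-fold lower. In none of these 5 lists did camera pass the threshold, with adjusted p = 0.197, 0.26, 0.113, 0.117 and 0.197 in the order given.

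Markers of other tissues moved on the same arrays. All 12 muscle markers were higher (median 0.39, camera adjusted p = 0.0018, or 0.578 with an estimated correlation). The largest rises were sls at 1.597 and bt at 1.36, which encode giant sarcomere proteins, and the smallest were Mlc1 at 0.19 and Prm at 0.17. Of 13 neuron markers 11 were higher and 1 lower (median 0.56, adjusted p = 0.00921; adjusted p = 0.578 with an estimated correlation), with brp at least 3.04-fold and futsch at least 2.57-fold higher, both dim in wild type. The cell cycle list had 1 higher and 10 lower of 13 (median -0.78, adjusted p = 0.0346; adjusted p = 0.578 with an estimated correlation), and fzy and dup fell by 2.29 and 1.58. That call was lost under 4 of 18 alternatives. Of 19 midgut markers 12 were higher and 7 lower, with Mal-A3 at 3.43 and betaTry, dim in wild type, at least 2.94-fold higher. Of 13 innate immunity genes 8 were higher and 3 lower, with PGRP-LE at 1.39 and Drs, dim in wild type, at least 1.52-fold higher. Glia markers had 3 higher and 3 lower of 7, with moody at 2.52, Gs2 at 1.15 and wrapper at -0.99. Hemocyte markers had 5 higher and 4 lower of 11, with NimC1, dim in grh mutant, at least 2.94-fold lower and Hml, dim in wild type, at least 1.12-fold higher. Hml and the neuron marker brp passed the filter only through grh mutant, so their rise was fixed.

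In the remaining lists, 2 of 4 fat body markers were higher and none lower, with Mtp at 0.54 and Apoltp at 0.45. Salivary gland markers had 2 higher and 2 lower of 4, with PH4alphaSG1 at -1.14 and PH4alphaSG2 at 0.78. Germline and maternal transcripts had 3 higher and 2 lower of 6, with stau at 1.23 and bcd, dim in grh mutant, at least 4.75-fold lower. Heat shock and stress genes had 1 higher and 4 lower of 6, with Hsp68 at -2.61 and Hsp26 at -2.12. Ecdysone pathway genes had 5 higher and 1 lower of 8, with Eip78C at 1.90 and br at 1.10. Ribosomal protein genes had 7 higher and 14 lower of 34, with RpS5b at -1.18 and RpL24-like at -0.75. The median and the mean differed in sign for glia (-0.08 and 0.28), salivary gland (0.11 and -0.04) and, before dim genes were set at their bound, germline and maternal transcripts (0.48 and -0.13; 0 and -0.04 at the bound). Hemocyte markers had a mean of -0.099 at the bound, and fry gave them a downward direction against a median of 0.03.

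Across all 8632 rows, limma called 3131 higher and 3848 lower in the arrays labelled grh mutant, 80.85% of those tested, and 929 and 609 changed at least 2-fold by the fitted values, or 814 and 530 with dim groups at their bound. Of the called rows 1.906% were dim in both groups. The groups did not overlap in 7797 rows, where chance gives 33.33%. With the small spread between replicates, most calls were small changes, and the array hybridisation controls were also lower, at 7.96 ± 0.14 against 8.79 ± 0.09 in wild type. The difference between the 3' and 5' control probe sets for Act5C, which follows RNA quality and labelling, was 2.20 ± 0.07 in grh mutant against 2.74 ± 0.06 in wild type and 2.74 ± 0.03 in grh overexpression, that for Gapdh was 1.002 ± 0.041, 0.981 ± 0.076 and 1.161 ± 0.087, and that for eIF4A was 1.041 ± 0.137, 1.084 ± 0.085 and 1.051 ± 0.081.

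The second comparison asked which transcripts differ between grh overexpression and wild type. Of 15 tested Osiris genes, members of a family active in cuticle-forming cells, 14 rose, and of 13 innate immunity genes 12 rose and 1 fell. Camera with an estimated correlation gave an adjusted p of 0.295 for each list. Osi1, Osi3, Osi5, Osi17, Mtk, PGRP-SB1 and PGRP-SC2 passed the filter only through the grh overexpression arrays, so their rise was fixed by the filter. Of 24 Osiris genes on the array, 15 were tested. Osi12 rose by 5.797 log2 units and Osi7 by 5.33, and Osi3, dim in wild type, was at least 28.5-fold higher (adjusted p = 1.73e-13). The cuticle protein gene Cpr64Ac was dim in wild type at 2.67 ± 0.05 and read 11.40 ± 0.01 in grh overexpression, at least 169.0-fold higher (adjusted p = 3.51e-15). Being dim in grh mutant too, it also passed the filter only through grh overexpression, so its rise was fixed. The gene kkv was 2.39-fold higher (adjusted p = 1.06e-10) and Ddc 1.31-fold higher (adjusted p = 3.62e-06), while vvl was 2.10-fold lower (adjusted p = 1.27e-06). All 12 muscle markers fell.

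Of the 10 largest fitted increases, 7 were dim in wild type. CG34227 was at least 274.9-fold, Fcp3C at least 144.2-fold, the alkaline phosphatase gene Alp9 at least 87.7-fold, the cytochrome P450 gene Cyp303a1 at least 75.3-fold, CG13258 at least 70.4-fold and CG32284 at least 41.1-fold higher, besides Cpr64Ac. At least Alp9 and Cpr64Ac among these passed the filter only through grh overexpression, so their rise was fixed. CG2444 was 206.2-fold higher, the ecdysone-inducible gene ImpE2 185.4-fold and Hpd, the gene of an enzyme of tyrosine breakdown, 184.1-fold. The genes hgo, which acts in the same pathway, and St2, both named because each group was measured, were 74.4-fold and 73.4-fold higher. Among the 10 largest fitted decreases, CG5402 was at least 54.5-fold, CG18581 at least 14.4-fold, GILT3 at least 12.7-fold, CG34290 at least 12.6-fold and CG30148 at least 8.68-fold lower. CG34276 was 55.3-fold, CG14453 38.6-fold, EAChm 28.3-fold, CG18649 22.6-fold and the lipocalin gene NLaz 22.0-fold lower, with both groups measured.

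None of the Osiris genes fell (median log2 fold change 2.12, or 1.74 with dim genes at their bound, camera adjusted p = 2.64e-07; adjusted p = 0.295 with an estimated correlation), and Osi24 rose by 3.05. Of 15 catecholamine and pigmentation genes 12 rose and 3 fell (median 0.99, adjusted p = 0.00926; adjusted p = 0.32 with an estimated correlation). The genes yellow-d2, ebony (e) and Pu rose by 2.85, 2.69 and 2.05 log2 units, and yellow (y) fell by 2.28. Of 83 cuticle protein genes 24 rose and 50 fell (median -0.67, or -0.48 with dim genes at their bound, adjusted p = 0.0298; adjusted p = 0.629 with an estimated correlation). TwdlO and Cpr47Ea, dim in wild type, were at least 9.68-fold and 5.63-fold higher, and Lcp65Af fell by 4.19. TwdlO, Cpr47Ea, Edg84A, Cpr60D and Cpr76Bc, among others, passed the filter only through grh overexpression, so their rise was fixed. Cpr65Au passed only through wild type, so its fall was fixed in both contrasts. The call of that list was lost under 6 of 18 alternatives, with adjusted p = 0.0563 without grh overexpression replicate 2. Innate immunity genes had 12 higher and 1 lower of 13 (median 1.05, or 0.99 with dim genes at their bound, adjusted p = 0.000566; adjusted p = 0.295 with an estimated correlation), with the antimicrobial peptide genes Drs and Mtk, dim in wild type, at least 6.50-fold and 2.54-fold higher.

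Chitin synthesis and cuticle assembly genes went both ways, with 11 higher and 10 lower of 24 (adjusted p = 0.436), and Cht5, dyl and knk rose by 5.07, 2.54 and 2.24, while dy, dim in wild type, was at least 5.29-fold higher. Of 14 denticle and zona pellucida domain genes 9 were higher and 4 lower (median 1.77, or 1.37 with dim genes at their bound, adjusted p = 0.0541), with mey at 2.66 and tyn, dim in wild type, at least 8.78-fold higher. Of these genes dy and sha passed the filter only through grh overexpression, so their rise was fixed. Wound response genes had 4 higher and 0 lower of 6 (adjusted p = 0.0541), with Gadd45 at 2.66 and msn at 0.64. Without wild type replicate 1 the adjusted p of both these lists was 0.0492. Of 10 earlier described Grh targets 6 were higher and 2 lower (camera adjusted p = 0.11), with sinu at -0.65. In that list msn, kkv and Ddc are also wound response genes. Septate junction genes had 2 higher and 15 lower of 22 (median -0.41, adjusted p = 0.025; adjusted p = 0.295 with an estimated correlation), and pasi2 and Cont fell by 1.26 and 0.84. Apical polarity and adherens junction genes had 5 higher and 4 lower of 12, with cno at 0.64, pyd at 0.59 and shg at 0.51. Of 12 tracheal genes 1 was higher and 8 lower (adjusted p = 0.0776), with kni at -1.22 and btl, dim in grh overexpression, at least 1.12-fold lower.

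On the same arrays, all 12 muscle markers were lower (median -0.75, adjusted p = 0.000179; adjusted p = 0.295 with an estimated correlation), and Obsc, Act87E and Mf fell by 1.96, 1.79 and 1.77. Glia markers had 0 higher and 6 lower of 7 (median -0.92, adjusted p = 0.0289; adjusted p = 0.295 with an estimated correlation), with wrapper at -1.56 and alrm at -1.24. Hemocyte markers had 1 higher and 9 lower of 11 (median -0.64, adjusted p = 0.025; adjusted p = 0.295 with an estimated correlation), with the prophenoloxidase genes PPO1 at -1.59 and PPO2 at -1.54. The cell cycle list had 9 higher and 0 lower of 13 (median 0.62, adjusted p = 0.00768; adjusted p = 0.356 with an estimated correlation), and dup, CycB3 and CycB rose by 2.20, 2.06 and 1.93. Of 13 neuron markers 2 were higher and 8 lower (adjusted p = 0.352), with VGlut at -0.65 and futsch, dim in wild type, at least 1.06-fold higher.

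Midgut markers had 12 higher and 6 lower of 19, with the maltase genes Mal-A1 at 3.81 and Mal-A3 at 3.79. Germline and maternal transcripts had 5 higher and 1 lower of 6, with bcd at 2.10 and spn-E, dim in wild type, at least 1.41-fold higher. Heat shock and stress genes had 2 higher and 4 lower of 6, with Hsp68 at -3.43 and Hsp26 at 2.30. Ecdysone pathway genes had 0 higher and 6 lower of 8, with Cyp18a1 at -1.52 and EcR at -0.60. Fat body markers had 1 higher and 3 lower of 4, with Fbp2, dim in wild type, at least 1.47-fold higher and Apoltp at -0.63. Their median was -0.26 against a mean of 0.28, or -0.15 with Fbp2 at its bound. Fbp2 passed the filter only through grh overexpression, so its rise was fixed. Salivary gland markers had 1 higher and 3 lower of 4, with PH4alphaSG2 at 1.06. Ribosomal protein genes had 7 higher and 4 lower of 34, with RpS5b at -0.87.

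In this comparison 3107 of 8632 rows were called higher and 3808 lower, 80.11% of those tested, and 1132 and 714 changed at least 2-fold by the fitted values, or 1005 and 634 with dim groups at their bound. Of the called rows 1.504% were dim in both groups. The groups did not overlap in 7730 rows, where chance gives 33.33%. Adjusted over the list alone, the counts of the 23 lists equalled those over all genes in both contrasts against wild type. With an estimated correlation camera called 0 lists in either contrast, while 1 list in grh mutant and 2 in grh overexpression had an unadjusted p under 0.05, and fry called 22 and 22 lists.

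**Figure D2:**
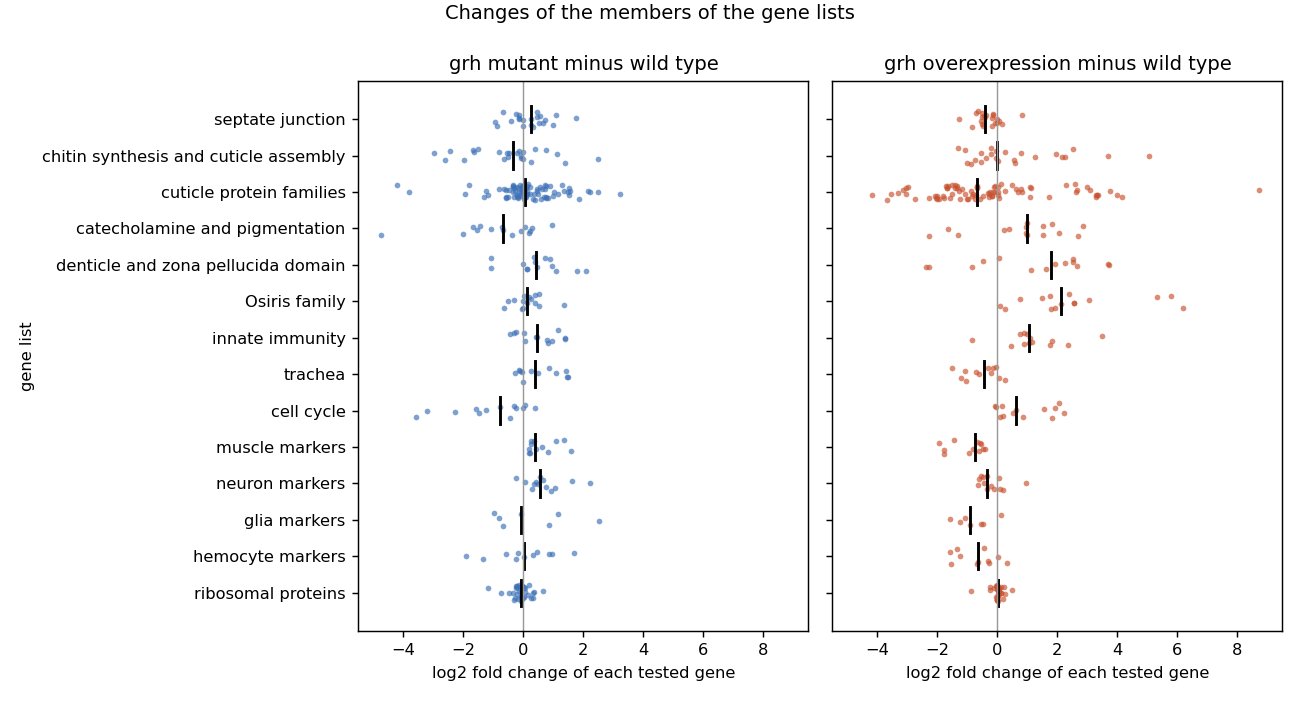
Log2 fold change (horizontal axis) of each tested gene of 14 lists (vertical axis) in grh mutant (left) and grh overexpression (right), each minus wild type; points are genes, spread vertically for legibility, and black lines are medians of the fitted changes, with genes of a dim group at their fitted value. The median of the Osiris family was 0.12 in grh mutant and 2.12 in grh overexpression, and that of the muscle markers 0.39 and -0.75.

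The third comparison set grh overexpression directly against the arrays labelled grh mutant. Its fold changes do not use the wild type arrays, which still entered the spread behind its p-values, the row filter and the choice of probe sets. Relative to grh mutant, Ddc was 3.59-fold higher (adjusted p = 2.12e-12), kkv 3.50-fold higher (adjusted p = 2.59e-12) and vvl 2.95-fold lower (adjusted p = 2.59e-08). Of the 23 lists, camera called 3 higher and 6 lower, and 0 with an estimated correlation. The lists called higher were the Osiris family (median 2.10, or 1.51 with dim genes at their bound), catecholamine and pigmentation (1.82) and the cell cycle (1.63, or 1.57 with dim genes at their bound), with adjusted p = 0.349, 0.385 and 0.459 with an estimated correlation. Muscle markers had 12 of 12 lower, neuron markers 13 of 13 and tracheal genes 9 of 12, each with adjusted p = 0.349 with an estimated correlation. The other lists called lower were septate junction, cuticle protein families and hemocyte markers, with adjusted p = 0.349, 0.691 and 0.349 with an estimated correlation. In all, 3707 rows were called higher and 3772 lower, 86.64% of those tested.

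Genes called in both contrasts against wild type went in opposite directions in 2832 rows and in the same direction in 2794, where independent lists would give 2766.2 and 2824.5. Among fitted changes of at least 2-fold, 172 rows were lower in grh mutant and higher in grh overexpression against 79.9 for independent lists, and 102 were lower in both against 50.4. Higher in both were 115 rows against 121.8, and 89 were higher in grh mutant and lower in grh overexpression against 76.8. With dim groups at their bound these counts were 132 against 61.7, 91 against 38.9, 85 against 94.8 and 75 against 59.8, in the same order. The genes yellow-d2, Hpd, KFase, insv and pim were lower in grh mutant and higher in grh overexpression, and CG15023 went the other way. Hpd read 2.34 ± 0.03 in grh mutant, 5.05 ± 0.13 in wild type and 12.58 ± 0.02 in grh overexpression, and pim, which encodes securin, read 3.85 ± 0.08, 6.42 ± 0.06 and 9.05 ± 0.08. CG30148, TwdlQ and NLaz were lower in both, and CG32284, Prx6c and Mal-A3 higher in both. Rows dim in both altered genotypes, CG30148 among them, passed the filter only through wild type, so their fall in both contrasts was fixed. The excess of rows lower in both over independent lists includes such rows, which were not counted apart, and so cannot be read as a shared response.

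Across rows, which are not independent replicates, the log2 fold changes of the contrasts had a Pearson r of -0.0034, where unchanged groups simulated against the same wild type arrays gave 0.5. Their covariance was -0.0033 against 0.0027 simulated, and 49.75% of rows had the same sign against 66.63%. The simulated groups differed only by the spread between replicates, which fixes these values. So 0.5 and 66.63% are not what to expect of groups that differ by more than that spread. Simulated unchanged groups gave 0 rows called in both contrasts, a value that likewise holds only where no row is changed. The wild type arrays cannot be split into parts of 2 arrays each, so part of any excess in the same direction may come from the shared arrays.

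**Figure D3:**
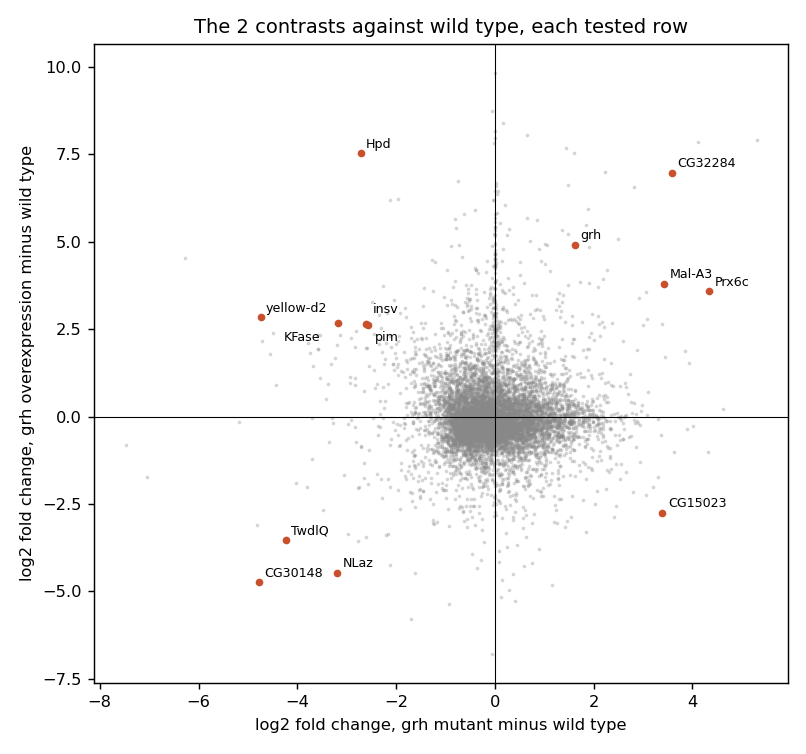
Log2 fold change of each of the 8632 tested rows in grh mutant minus wild type (horizontal axis) and grh overexpression minus wild type (vertical axis); each point is a row, and grh and the 12 genes named for both contrasts are coloured, with genes of a dim group at their fitted value. The gene grh lies at 1.62 and 4.92, NLaz at -3.20 and -4.46, and Mal-A3 at 3.43 and 3.79.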

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

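The comparisons between tissue markers and the medians and counts with dim genes at their bound were chosen only after the result was seen, and so was the decision to set aside the test of other probe sets. Control probe sets outside the comparisons stood above wild type. Array-control actin probe sets read 11.71, 10.3, 10.87 and 10.24 in grh overexpression against 10.18, 8.74, 9.6 and 8.32 in wild type. Another control probe set read 5.17 in grh mutant against 4.12 in wild type. Groups of 2 arrays did not allow a test for single arrays that stand apart.

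Of 13 cell cycle genes 10 were lower and 1 higher in grh mutant and 9 were higher and 0 lower in grh overexpression (camera adjusted p = 0.578 and 0.356 with an estimated correlation). The pattern as set down before the next test also held maternal transcripts, so a test on maternal genes partly restates it. One candidate explanation is a different share of unfertilised eggs or very young embryos: the 7 tested strictly maternal genes had a median log2 fold change of -1.633 (95% interval -2.455 to -0.651) in grh mutant and 1.978 (1.143 to 2.357) in grh overexpression, which met both conditions set beforehand; with dim genes at their bound the medians were -0.651 (-1.022 to -0.533) and 1.978, so that the condition held in grh overexpression and stays open in grh mutant, where 5 of the 7 had a dim group. Of the 7 tested, del passed the filter only through grh overexpression, at 3.09, 2.44 and 8.11 in grh mutant, wild type and grh overexpression, so its rise there was fixed. Against a large share, 10 of the 17 matched maternal genes stayed dim, with alphaTub67C at 2.31, 2.37 and 3.23 and wisp at 2.29, 2.37 and 3.82 in the same groups. Yet 7 of these 10 followed the same order, and values near the floor exclude nothing. A change in cell division was not settled, since 11 replication genes outside the list had medians of -0.563 (-0.895 to -0.207) and -0.269 (-0.531 to 0.703), or -0.349 (-0.804 to -0.133) and -0.133 (-0.403 to 0.346) with dim genes at their bound. Among them RfC3 passed the filter only through wild type, so its fall in both contrasts was fixed. Psf2 passed only through grh overexpression, so its rise there was fixed. The grh genotype itself stays open and untested as a cause.

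In grh overexpression, 254 rows that were dim in wild type rose by at least 2 log2 units by the fitted values, and 221 of them were dim in grh mutant too; at the bound 126 of the 254 did so, 103 of these dim in grh mutant too. Tissue of adults or late pupae is argued against, since 1 of 22 such transcripts (Yp3, 4.51 in wild type and 5.62 in grh overexpression), 4.55% (exact 95% interval 0.115% to 22.8%), lay above the filter and above wild type. Cross-hybridisation stays open: among the 225 named genes of this pattern, 11 had another probe set, whose highest change had a median of 0 (0 to 0.095), and in 2 of them it rose by at least 1 log2 unit. The median met the condition set beforehand for cross-hybridisation, but after the value was seen the test was set aside as void, because it covers 4.89% of the genes and because the other probe sets are the dimmer ones by construction. An effect of the overexpressed factor stays open and untested.

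In grh mutant 12 of 12 muscle and 11 of 13 neuron markers were higher, and in grh overexpression 12 of 12 muscle markers were lower (camera adjusted p = 0.578, 0.578 and 0.295 with an estimated correlation). The rise of the neuron marker brp in grh mutant was fixed by the filter. Older grh mutant and younger grh overexpression embryos stay open: 9 early patterning genes had medians of 0.818 (-0.317 to 1.12) and -0.142 (-0.985 to -0.023), or 0.456 (-0.317 to 1.059) and -0.11 (-0.985 to 0) with dim genes at their bound, so that the bound set beforehand against younger embryos was met only by the fitted values. Of the 9, slp2 passed the filter only through grh mutant, so its rise there was fixed. A changed share of another tissue would move these markers alike: muscle minus hemocyte in grh mutant was 0.361 (-0.472 to 1.184), which leaves this open, and neuron minus hemocyte was 0.538 (-0.296 to 1.234, or 0.043 to 1.234 with dim genes at their bound, and then -0.296 to 1.901 over 6 pairs of tissues together). In grh overexpression muscle minus neuron was -0.397 (-1.32 to -0.149, and -1.604 to -0.067 over the pairs together), which argues against an equal fall of these 2 lists. Neuron minus glia was 0.568 (0.045 to 1.145, and -0.465 to 1.337 over the pairs together). Muscle minus hemocyte was -0.104 (-1.077 to 0.665) and muscle minus glia 0.17 (-0.891 to 0.641). Intervals are over genes and not embryos, and muscle markers alone ran from -0.423 (Mlc1) to -1.956 (Obsc). A fall of all tissues alike is therefore not settled. An effect of genotype on these tissues stays open and untested. So does one of RNA quality or labelling: the Act5C 3' minus 5' difference was 2.202 in grh mutant against 2.741 in wild type. Those of Gapdh (1.002 against 0.981) and eIF4A (1.041 against 1.084) differed less.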

How the results depend on the processing

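All alternatives were chosen before the data were examined. The one for linear values did not apply, since the values are on a log scale. Counts of called rows stayed within 1.5 times under all alternatives but a minimum fitted change of 1 log2 unit, which gave 929 higher and 609 lower (grh mutant), 1132 and 714 (grh overexpression), 1611 and 1503 (grh overexpression minus grh mutant), and 217 in the same and 261 in opposite directions, through its own construction. Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 2938 to 3076 higher and 3609 to 3791 lower in grh mutant, 2822 to 3070 and 3443 to 3736 in grh overexpression, 3485 to 3717 and 3546 to 3783 between these, and 2523 to 2657 in the same and 2511 to 2609 in opposite directions. With 2 numbers per group, the replicate numbers were not taken to pair the arrays. Deviations of same-numbered arrays correlated at 0.1651, 0.2449 and 0.1364, and the replicate block gave 3218 and 3953, 3185 and 3942, 3789 and 3848, 2972 and 2985 rows in the order above, with 1 list call lost (cell cycle in grh mutant, adjusted p = 0.0548, and 0.00029 to 0.578 over its alternatives) and 1 gained (ecdysone pathway in grh overexpression minus grh mutant, adjusted p = 0.0432, and 0.000492 to 0.511 over its alternatives). The latter was also called without grh mutant replicate 1 (adjusted p = 0.0454) and without grh overexpression replicate 2 (adjusted p = 0.0466).

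Of 3742 comparisons for 236 named-gene results, 3730 kept direction and call, 9 lost the call, 1 gained it and 2 reversed: ftz-f1 read -0.51 in both contrasts but 0.29 (grh mutant) and 0.275 (grh overexpression) as the mean of its probe sets. Of 1239 comparisons for 69 list results, 1139 kept both, 29 lost the call, 67 gained it and 4 reversed. Fry reversed earlier described Grh targets (median 0.366), germline and maternal transcripts (0.483) and hemocyte markers (0.026) in grh mutant and fat body markers (-0.26) in grh overexpression. An estimated correlation ended all 21 list calls, and the cause was not tested. Probe sets near the floor of 2.27 limit what can be seen of low transcripts.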

Other observations

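All gene groups in this part were chosen after their values were seen. Of 6 tested genes for enzymes of tyrosine breakdown 5 rose in grh overexpression, and in grh mutant 5 fell and 1 rose. From wild type to grh overexpression, Hpd went from 5.05 to 12.58, hgo from 4.22 to 10.44 and Faa from 6.51 to 8.75 (limma adjusted p = 9.09e-15, 2.78e-13 and 1.79e-10). In grh mutant Faa fell by 1.70 log2 units and GstZ1 rose by 0.23, while Hpd, GstZ2, hgo and Tat, dim there, were at least 2.07-fold, 2.73-fold, 1.17-fold and 1.13-fold lower. Tat in grh overexpression differed by 0.12 (adjusted p = 0.211).

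Of 7 tested alkaline phosphatase genes 1 was higher (Alp1, dim in both groups) and 3 were lower in grh mutant, and 3 were higher and 3 lower in grh overexpression. Alp9, Alp1 and Alp10 were dim in wild type and grh mutant, so they passed the filter only through grh overexpression, where they read 10.45, 8.76 and 7.24. Alp12 fell by 1.06 log2 units in grh overexpression. Of 8 maltase genes 5 were higher and 3 lower in each contrast, with Mal-A8, among the higher, dim in both groups of the grh mutant contrast. Mal-A3, Mal-A1 and Mal-A6 rose in both, and Mal-A4 fell by 0.64 log2 units in grh mutant and rose by 1.86 in grh overexpression.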
